A study of Drosophila melanogaster with 3 samples.

How the data were processed

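The samples are 3 biological replicates of a single group: whole white prepupae of Drosophila melanogaster, of both sexes, from a line with CG31627 fused to GFP at its C-terminus. Per the labels, chromatin was sheared by sonication with a fragment size range of 200 to 800 bp, and the immunoprecipitation used an antibody to GFP; another label names the antibody after CG31627, the tagged protein. The replicate numbers are those of the labels. Nothing in the labels puts the libraries in batches.

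The deposited files are 10 peak lists in narrowPeak format: for each of the builds dm6 and dm3, a list per library, a list for the pooled libraries and a list of peaks past a threshold on the irreproducible discovery rate (IDR). The signal value of each peak is the authors' own, as deposited; its scale is not given in the sources used here, so it served only to rank and describe peaks within a list. The q value of each peak is deposited as −log10 and has a ceiling shared by many peaks. Per the deposited listing, the lists of single libraries and of the pooled libraries hold background on purpose, as input to the IDR step, and derive from alignments plus a further file from which the control-normalized tracks also derive. Those signal tracks were not used here. The aligner, the peak caller and their versions are not given in the sources used here. Control data were not analysed here. The files hold no read counts, so depth and counting intervals are not given. No line was identical between the lists of any pair of libraries. On dm6, 54 IDR-thresholded peaks repeat the interval of another with a different summit, and were kept.

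Coordinates were used with the Ensembl release 115 annotation and the Release 6 genome sequence, which have the chromosome names and lengths of dm6. Genes on the 6 arms 2L, 2R, 3L, 3R, 4 and X were used, 18164 in all, without transposable elements. One peak on chromosome Y in the list of replicate 2 was left out. Positions on dm3 were compared only with each other, since the box held no annotation of that build.

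Peaks were represented by their summits. For each library, the 7717 strongest peaks on the 6 arms were taken, as many as there are IDR-thresholded peaks, and values are given as mean and SD over the 3 libraries. A summit within 500 bp of any annotated start site was a promoter summit; the rest were assigned in the order 5′ UTR, coding sequence, 3′ UTR, non-coding exon, intron, intergenic. Chance came from 1000 circular shifts of the peaks along each arm; the smallest p these give is 0.002 two-sided and 0.001 one-sided. Gene lists were tested with Fisher's exact test against all other genes. Motifs on either strand within 50 bp of the summit were tested with the exact McNemar test against a window of the same width centred 500 bp away on a side drawn at random, and 8-mers in the same way, with reverse complements as one. Arms were tested with the exact binomial test against their length. Median signal was tested by permutation with 100000 resamples. Tests were two-sided unless stated, and p was adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05.

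The 27 gene lists, the 20 motifs and the rule for named genes were fixed before the data were examined. The rule took the genes nearest to, and within 500 bp of, the summits of the 25 strongest IDR-thresholded promoter peaks that also lay among the strongest peaks of all 3 libraries; up to 4 bound members of each list with the strongest promoter peak; CG31627 itself; and every bound member of the ecdysone and Hox lists. Members absent by symbol were matched through older symbols; 1 of the 10 germline genes could not be matched to a single gene, which left 9. Ranks are by signal within the IDR-thresholded peaks.

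Alternatives were other promoter windows, the 3858 peaks with the highest signal, protein-coding genes alone, other overlap rules, other backgrounds, dm3 lists and leaving out each replicate in turn; for peaks, the last took IDR-thresholded peaks among the strongest of both other libraries. Mappability was measured as the share of 31-mers that occur once in the reference, and genes with at least 80% unique 31-mers around their start sites, 17339 of them, were used in a further alternative. That alternative, and those on the 5250 pooled peaks below the IDR threshold with a q value of 0.05 or less, were chosen after seeing the data.

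The statistics were tested on simulated data. For location, 39.4% of 4000 simulated summits fell in promoters where 39.5% had been placed. For gene lists, 87.8% of 180 lists simulated with more bound genes were called, 51.7% of 180 with fewer, and 2.22% of 180 left at the background rate. The simulated lists drew genes at random, so they did not cover lists whose members lie close together. For motifs, the DRE was found in 4.9% of 4000 windows, where 5.35% was expected from inserting it at random. For 8-mers, the inserted word ranked 1 by p. No motif or 8-mer was called in the 4000 windows before insertion. For arms, 1 of 120 was called in sets placed at random. For signal, 6% of 50 unchanged sets were called. For library overlap, 80.1% of 4000 simulated peaks were found shared where 80% had been placed. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.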

Results

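Sites bound by CG31627 were mapped by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster at the white prepupal stage, the hours around the onset of metamorphosis. The protein carried GFP at its C-terminus and was precipitated with an antibody to GFP. The 3 libraries are biological replicates of a single group, males and females together, so the design gives comparisons of library with library and of peaks with the rest of the genome. The deposited peak lists held 30000, 28593 and 25547 peaks for replicates 1, 2 and 3, of which 17347, 8592 and 10806 had a q value of 0.05 or less. The list of replicate 1 ended at exactly 30000 peaks on both genome builds. A list called on the 3 libraries pooled held 27240 peaks, and 7717 of these passed the authors' threshold on the irreproducible discovery rate (IDR). These 7717 peaks, the IDR-thresholded peaks, were the 7717 strongest of the pooled list and had a median width of 404 bp. The lists hold no read counts, so the depth behind each value is unknown. All coordinates are on dm6.

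The first question was where along genes CG31627 bound. Its summits gathered at promoters and were nearly absent from coding sequence. Of the 7717 summits, 3223 (41.8%) lay within 500 bp of an annotated start site, 3.08 times the 13.6% reached when the peaks were shifted along the chromosome arms. Only 13 summits (0.168%) fell in coding sequence outside promoters, where shifted peaks put 13.7%. The 3′ UTRs held 0.842% against 4.45% by chance, the 5′ UTRs 0.428% against 0.778%, and intergenic sequence 16.9% against 27.2%. Introns held 39.1% of the summits, close to the 39.5% of shifted peaks, and non-coding exons 0.855% against 0.813%. The shifts took no account of mappability. Unique 31-mers made up 82.2% of introns and intergenic sequence, against 98% of coding sequence. Chance shares in introns and intergenic sequence may thus be too high.

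The promoter, 5′ UTR, coding, 3′ UTR and intergenic shares lay outside all 1000 shifts (circular-shift permutation, two-sided, adjusted p = 0.0028, from the smallest unadjusted p these shifts allow). The intron and non-coding exon shares did not pass the permutation test (adjusted p = 0.705 for both). Among the 7717 strongest peaks of each library, the promoter share was 41.4% ± 2.62 (SD, n = 3) and the coding share 0.225% ± 0.0665 (SD, n = 3). The intron share depended on the promoter window: it stood at 1.06 times chance with 250 bp and 0.896 times with 1000 bp, both past the test.

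**Figure D1:**
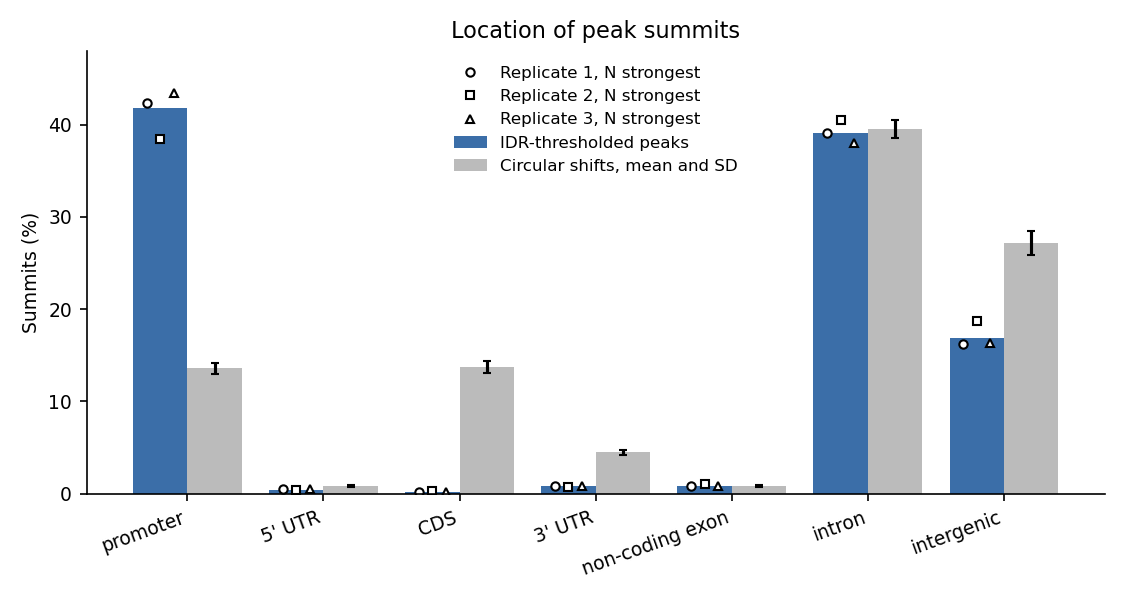
Share of peak summits (%, y axis) in each annotation class (x axis) for the 7717 IDR-thresholded peaks (blue bars), for the 7717 strongest peaks of each library (black symbols) and for 1000 circular shifts (grey bars, mean with SD). Promoters hold 41.8% of the summits against 13.6% by chance, and coding sequence 0.168% against 13.7%.

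The strongest promoter peak, first in the pooled list and in each of the 3 libraries, lay 87 bp from the start site of CG14100 (FBgn0036889), on 3L from 19590379 to 19590845, with an authors' signal value of 6697. Chro (FBgn0044324), which encodes the chromatin protein Chromator, ranked 4 of 7717 with a peak on 3L from 22878668 to 22879140. Ugalt, a UDP-galactose transporter, ranked 3 (X from 2703674 to 2704116) with a summit 38 bp from its start site. The exoribonuclease gene PNPase ranked 6 (3R from 31404439 to 31404909), the arginine methyltransferase gene Art3 ranked 10, and the RNA-binding protein gene larp ranked 17. The mitochondrial ribosomal protein gene mRpL41 ranked 15 and the Polycomb group gene ph-p (FBgn0004861) ranked 22. Sox14, a Sox family transcription factor, ranked 29 with a peak on 2R from 23978333 to 23978786. Also among the 25 strongest reproducible promoter peaks were those of CG1888, Tcs5, CenG1A, CG8320, CG31145, CG5098, GstE13, Atat, CG18549, CG9147, Trp1, Pal1 and gish, and of the non-coding RNAs asRNA:CR45928, lncRNA:CR44619 and lncRNA:CR31044. At the gene of the tagged protein itself, CG31627 (FBgn0051627, 2L from 21173222 to 21174179), the nearest IDR-thresholded summit lay 4770 bp away. In the library lists, background included, the nearest summits lay 3877, 4769 and 4720 bp away in replicates 1, 2 and 3.

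The next comparison asked which groups of genes carried CG31627 at their promoters. Of 18164 genes, 4048 (22.3%) had an IDR-thresholded summit within 500 bp of a start site. Both lists of ribosomal protein genes stood above this. Cytosolic ribosomal protein genes were bound in 71 of 85 cases (83.5%), against 22% of other genes, with RpS27 (3R from 25247355 to 25247758), RpL32, RpL7 and RpL34b carrying the strongest peaks. Mitochondrial ribosomal protein genes were bound in 38 of 73 cases (52.1%), and mRpS10, mRpS23, mRpL41 and mRpL23 ranked 10, 12, 15 and 44 among all peaks. The mRpS10 and mRpS23 peaks are those of Art3 and CenG1A, whose start sites lay nearer the summits (for CenG1A 106 bp, against 386 bp for mRpS23).

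Genes of chromatin and of the cell cycle were also bound more often than other genes. Chromatin and insulator protein genes were bound in 17 of 29 cases (58.6%), led by Chro, ph-p, the insulator cofactor gene Cp190 and brm, the ATPase of the Brahma remodelling complex. Cell cycle and DNA replication genes were bound in 16 of 30 cases (53.3%), among them Dp, the helicase subunit gene Mcm2, the kinase gene aurA and Cdk1. Proteasome genes were bound in 15 of 32 cases (46.9%), with Rpn5, Rpn3, Rpt5 and Rpn6 strongest. Heat shock genes were bound in 9 of 19 cases (47.4%), led by Hsp27 (rank 65, 3L from 9383698 to 9384121), lncRNA:Hsromega, Hsp26 and Hsc70-4; among the 13 with unique promoter windows the 9 made 69.2%. Oxidative phosphorylation genes were bound in 26 of 76 cases (34.2%), with the complex I genes ND-MWFE, ND-ASHI, ND-42 and ND-51 strongest.

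Genes of the ecdysone response, the hormonal programme that drives the prepupal stage, were bound in 10 of 23 cases (43.5%). They were Eip63F-1 (rank 378), Eip75B (rank 530, 3L from 17999607 to 17999986), usp (rank 1443), Eip74EF (rank 3065), ImpE3 (rank 3127), tai (rank 4103), ImpL2 (rank 4709), EcR (rank 5371, 2R from 6157444 to 6157605), rig (rank 6454) and br (rank 7078). EcR and usp encode the 2 subunits of the ecdysone receptor, and Eip74EF, Eip75B and br encode early response transcription factors. The peaks of tai (rank 8065 in replicate 2), rig (rank 9496 in replicate 1) and br (rank 10000 in replicate 1) lay outside the 7717 strongest of that library. The other bound members lay among the 7717 strongest of all 3 libraries.

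No promoter peak lay at any of 98 cuticle protein genes, 22 salivary gland secretion genes, 14 antimicrobial peptide genes or 8 Hox genes. Chemoreceptor and odorant-binding protein genes were bound in 4 of 237 cases (1.69%), namely Obp83g, Ir60e, Obp99b and Gr63a. The Gr63a peak ranked 17317 in replicate 2, outside its 7717 strongest. Digestive enzyme genes were bound in 1 of 38 cases, Mal-A5, and imaginal disc patterning genes in 1 of 34, the eye selector gene so. Cytochrome P450 genes were bound in 6 of 85 cases (7.06%), with Cyp6u1, Cyp6v1, Cyp6a2 and Cyp317a1 strongest. None of the 111 replication-dependent histone genes had a promoter peak, and none of them had promoter windows with at least 80% unique 31-mers, so binding there was not measurable from these lists. Among genes of small RNAs, tRNA genes were bound in 23 of 290 cases (7.93%), led by tRNA:Tyr-GTA-1-8, and snoRNA genes in 17 of 269 (6.32%), led by snoRNA:Psi28S-2949.

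The remaining lists did not pass the test, among them the unbound antimicrobial peptide and Hox genes. Aminoacyl-tRNA synthetase genes were bound in 11 of 32 cases (SerRS, IleRS, ThrRS and AspRS strongest), Notch pathway and E(spl) complex genes in 6 of 17 (E(spl)m3-HLH strongest), and fat body genes in 5 of 13 (Lpin strongest, at rank 91). Muscle structural genes were bound in 3 of 18 cases (sls, Tm1 and Mef2), germline genes in 2 of 9 (piwi and vas), neuronal genes in 1 of 17 (elav) and hemocyte genes in 1 of 9 (PPO3). The vas peak ranked 9130 in replicate 2, outside its 7717 strongest. The snRNA genes were bound in 6 of 32 cases, with snRNA:U6:96Ac and snRNA:U6:96Ab sharing the strongest peak.

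In all, 8 of the 27 lists were bound more often than other genes and 9 less often (two-sided Fisher's exact test, Benjamini-Hochberg over 27 lists). The 9 include the histone list, where 0 of 111 was set by the lack of unique windows, so its test says nothing about binding. Adjusted p was 1.06e-31 for cytosolic ribosomal proteins, 1.36e-07 for mitochondrial ribosomal proteins, 8.47e-05 for chromatin and insulator proteins and 6.05e-04 for cell cycle genes. It was 0.00477 for the proteasome, 0.0323 for oxidative phosphorylation, and 0.035 for both heat shock and ecdysone genes. Among lists bound less often it was 2.13e-19 for chemoreceptors and odorant-binding proteins, 9.35e-12 for snoRNA genes, 1.30e-10 for cuticle proteins and 3.55e-10 for tRNA genes. It was 8.96e-04 for cytochrome P450 genes, 0.00336 for digestive enzymes, 0.00673 for imaginal disc patterning and 0.0151 for salivary gland secretion. Fisher's test treats genes as independent, while neighbouring genes of a list can share a peak, as snoRNA:Psi28S-2949 and snoRNA:Or-aca5 did. For lists with clustered members these p values may be too small. Each of the 8 higher lists was higher in all 3 libraries, and each of the lower lists apart from histones was lower in all 3. In the 7717 strongest peaks of each library the bound share was 81.2% ± 8.24 (SD, n = 3) for cytosolic ribosomal protein genes, 46.4% ± 5.02 (SD, n = 3) for ecdysone genes and 1.02% ± 1.02 (SD, n = 3) for cuticle protein genes.

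Several calls rested on the setting. Against protein-coding genes alone, the ecdysone, oxidative phosphorylation and heat shock lists no longer passed (adjusted p of 0.149, 0.2 and 0.158). In the same exact test, the ecdysone call was also lost without replicate 2 (adjusted p = 0.108) or 3 (0.235), the proteasome call without replicate 1 (0.103) or 3 (0.11), and the oxidative phosphorylation call without replicate 1 (0.0621), 2 (0.0695) or 3 (0.117). In the 3858 peaks with the highest signal, the ecdysone, proteasome, oxidative phosphorylation, heat shock and cell cycle calls were lost (adjusted exact p of 0.342, 0.746, 0.181, 0.181 and 0.121). So were the salivary gland (0.188), digestive enzyme (0.121), cytochrome P450 (0.121) and disc patterning (0.0546) calls. With a 1000 bp window the oxidative phosphorylation (0.0629), disc patterning (0.175) and snoRNA (0.198) calls were lost and antimicrobial peptides passed (0.0309), and among genes with unique windows the ecdysone call was lost (0.0705) at a similar difference from other genes, 20.3 against 21.2 percentage points. Against circularly shifted peaks in place of other genes, 11 lists were bound more often, with aminoacyl-tRNA synthetases (adjusted permutation p = 0.00599), Notch pathway and E(spl) genes (0.018) and fat body genes (0.0162) now past the test. Of the lists bound less often only cuticle proteins and the chemoreceptor list passed. The tRNA, snoRNA and cytochrome P450 genes stood 2.64, 1.03 and 1.15 percentage points above the shifted share, none past the permutation test. Shifting takes away the general gathering at promoters, and 22.3% of all genes were bound. Lying above shifts thus does not set a list apart from other genes. The shifted share was highest for ecdysone genes, at 12.1% against 5.84% for cytosolic ribosomal protein genes, which Fisher's test does not allow for.

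**Figure D2:**
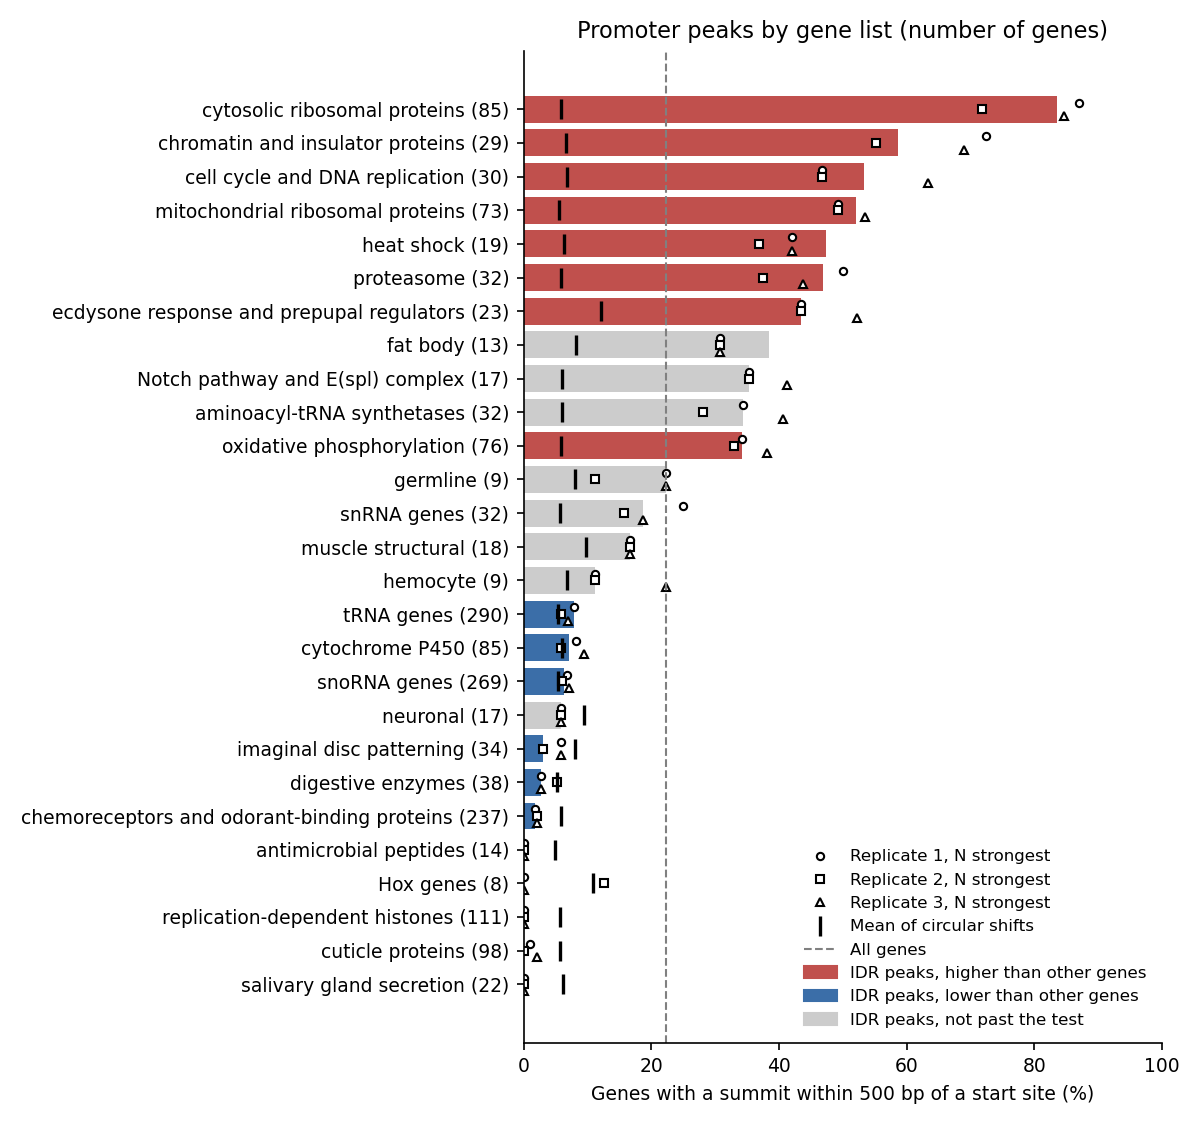
Share of genes (%, x axis) with a summit within 500 bp of a start site for each gene list (y axis, number of genes in brackets). Bars give IDR-thresholded peaks, coloured by the Fisher test (histone genes lack unique windows); symbols give the 7717 strongest peaks of each library, ticks the mean of 1000 circular shifts, and the dashed line the 22.3% of all genes. Cytosolic ribosomal protein genes reach 83.5% and cuticle protein genes 0%.

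Sequence under the summits was searched for 20 motifs fixed beforehand and for all 8-mers. At promoter peaks, 4 motifs known from housekeeping promoters were more frequent than in flanks. The DNA replication-related element (DRE, TATCGATA) lay within 50 bp of 3.69% of the 3223 promoter summits, against 0.341% of windows 500 bp away. Ohler motif 7 was found at 11.1% of promoter summits against 3.32% in flanks, the core motif of the insulator protein BEAF-32 (CGATA) at 22.6% against 12.3%, and Ohler motif 1 at 1.68% against 0.341%. Every DRE match is also a BEAF core match, so the counts of these motifs overlap. A motif that sits near start sites could differ from flanks in this way at any promoter. Promoters without a peak were not searched for motifs, so a preference among promoters cannot be read from this comparison. None of these 4 motifs passed the test at the 4494 other summits, where the DRE lay at 0.334% against 0.156% and Ohler motif 7 at 2.56% against 3.2%. Ohler motif 6, of the same family, did not pass at promoters, with 1.58% against 0.962% (exact McNemar test, adjusted p = 0.0587), and passed elsewhere, with 1.09% against 0.534% (adjusted p = 0.0103). The Su(Hw) motif was more frequent at both kinds of summit, with 2.58% against 0.652% at promoters and 2.71% against 1.78% elsewhere. The CTCF motif went in opposite directions, with 4.65% against 3.2% at promoters and 3.09% against 4.18% elsewhere.

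Repeat motifs and E-boxes were scarcer at summits than in flanks. The GAGA factor motif lay at 0.933% of all 7717 summits against 2.42% of flanks, the CA repeat at 0.713% against 3.54%, and the E-boxes CACGTG and CAGCTG at 0.622% against 1.57% and 3.08% against 4.57%. At promoter peaks alone the GAGA factor motif did not pass, with 1.18% against 1.74% (exact McNemar test, adjusted p = 0.104), while the other 3 did. Against dinucleotide-shuffled summit windows the GAGA factor motif, CAGCTG and the CA repeat turned from scarcer to more frequent, at 1.76, 2.36 and 1.83 times the background. The CTCF motif, not past the test against flanks over all summits, was more frequent there too, at 3.74% against 1.5% (exact McNemar test, adjusted p = 2.45e-18). The same background ended the calls for GATA, Pho and CRE (exact McNemar test, adjusted p of 0.139, 0.791 and 0.791), and left 10 motifs more frequent and 2 scarcer. It also ended the call for the TATA box, which lay at 8.8% of summits, 3.94% of flanks and 8.67% of shuffled windows.

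Over all summits, 8 motifs were more frequent than in flanks and 6 scarcer (exact McNemar test, two-sided, Benjamini-Hochberg over 20 motifs). Adjusted p was 6.50e-23 for the DRE, 4.53e-18 for Ohler motif 7, 3.80e-15 for the BEAF core, 2.44e-08 for Ohler motif 1 and 3.62e-07 for Su(Hw). Among the 7717 strongest peaks of each library the DRE lay at 1.75% ± 0.29 (SD, n = 3) of summits and 0.263% ± 0.0863 (SD, n = 3) of flanks.

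**Figure D3:**
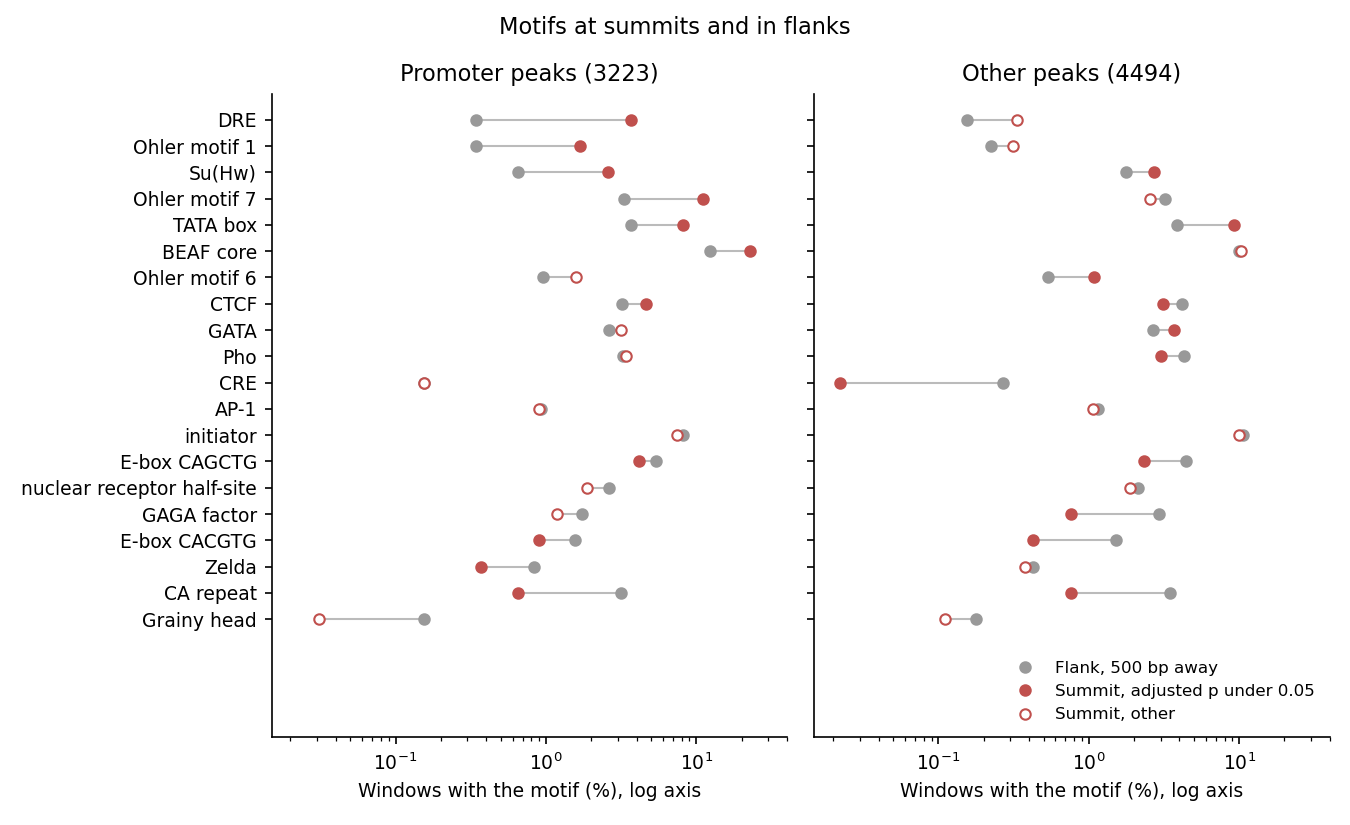
Share of windows reaching 50 bp to either side (%, x axis, log scale) with a match to each motif (y axis) at summits (red) and in flanks 500 bp away (grey), for 3223 promoter peaks (left) and 4494 other peaks (right); filled red points passed the exact McNemar test. The DRE lies at 3.69% of promoter summits against 0.341% of their flanks.

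The open search found AT-rich words. Of the 10 8-mers with the smallest p, 8 held A and T alone, led by TTTAAAAA at 6.12% of summits against 1.68% of flanks (exact McNemar test, adjusted p = 1.13e-42). The other 2 were CACACACA and ACACACAC, both scarcer at summits. ATCGATAG, which overlaps the DRE, lay at 1.8% of summits against 0.22% of flanks (exact McNemar test, adjusted p = 1.05e-21). Within 50 bp of the summit, bases were A or T in 64.4% of positions at promoter peaks and 67.2% at other peaks, against 57.8% over the 6 arms. The AT share at the 7717 strongest summits of each library was 65.7% ± 0.254 (SD, n = 3), and 56% ± 0.0828 (SD, n = 3) at 500 bp on either side. The exact McNemar test called 2896 8-mers as more frequent and 4178 as scarcer among 32896. Of those more frequent, 132 held A and T alone. No shuffled background was run for 8-mers, so a preference for single words of A and T cannot be told apart from base composition.

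**Figure D4:**
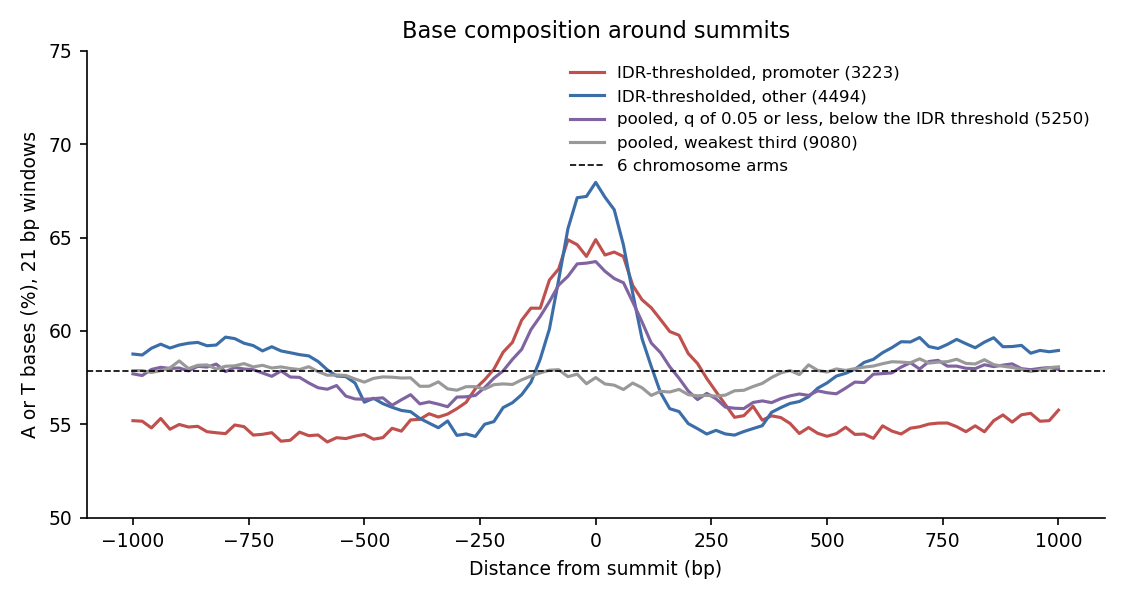
Share of A or T bases (%, y axis, 21 bp windows) by distance from the summit (bp, x axis) for promoter and other IDR-thresholded peaks, for pooled peaks below the IDR threshold with a q value of 0.05 or less, and for the weakest 9080 peaks of the pooled list; the dashed line is the mean of the 6 arms, 57.8%. The central window reaches 64.9% at promoter peaks and 68% at other peaks, and 57.5% in the weakest peaks.

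Peak signal was compared between promoters and other places within each list. Promoter peaks were the stronger ones: their median authors' signal value was 223, against 197 at the other IDR-thresholded peaks, a difference of 25.9 (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest possible). Among the 7717 strongest peaks of each library the medians were 90.5 against 83.4 in replicate 1 (permutation p = 7e-05), 58.8 against 47.7 in replicate 2 and 74.6 against 67.6 in replicate 3 (permutation p = 1e-05 in both). In the whole lists, which hold background, the medians were 27.9 against 18.1 in replicate 1, 21.8 against 13.8 in replicate 2 and 29.3 against 18.6 in replicate 3 (permutation p = 1e-05 in each). Promoters held 53% of the strongest 772 IDR-thresholded peaks and 36.4% of the weakest 771. Restricted to peaks among the strongest of the other libraries, the difference was 47.1 without replicate 3, 38 without replicate 1 and 28.6 without replicate 2.

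Across chromosomes, the small and largely heterochromatic chromosome 4 stood apart. It held 28 peaks, or 20.8 per Mb, 0.36 times its share by length (exact binomial test, two-sided, adjusted p = 7.37e-10). Chromosome X held 62.9 peaks per Mb, 1.09 times its share (exact binomial test, adjusted p = 8.37e-04), and 2R 53.5 per Mb, 0.929 times (0.00497). Arms 2L, 3L and 3R, with 59.5, 58.8 and 56.2 peaks per Mb, did not pass the test. Arm lengths were not corrected for mappability. Among the 7717 strongest peaks of each library the density was 24 ± 6.04 per Mb (SD, n = 3) on chromosome 4, 62.9 ± 2.15 on X and 53.9 ± 1.04 on 2R. The calls on X and 2R were lost in the 3858 peaks with the highest signal (exact binomial test, adjusted p of 0.689 and 0.134), where chromosome 4 stood at 0.206 times its share. With genes in place of length, chromosome 4 stood at 0.559 and X at 1.24 times their share, and 2L turned from 1.03 to 0.911 times.

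Libraries were compared peak by peak. Of the IDR-thresholded peaks, 97.9% ± 1.44 (SD, n = 3) had their summit in a peak of a library's whole list, and 89.1% ± 2.06 (SD, n = 3) in one of its 7717 strongest peaks. By library the latter share was 90.6%, 86.8% and 90% for replicates 1, 2 and 3, where shifted peaks reached at most 2.8%. The IDR-thresholded peaks were the strongest of a list called on these same libraries pooled, so a share above chance was built in. All 3 libraries shared 5737 of the peaks (74.3%) at this depth and 7251 (94%) in the whole lists, and 23 peaks were among the strongest of no library. Sharing at this depth fell with signal, from 99.4% of the strongest 772 IDR-thresholded peaks to 5.32% of the weakest 771. Across peaks found in both libraries of a pair, Spearman's correlation of the authors' signal values was 0.848 for replicates 1 and 2, 0.849 for 1 and 3 and 0.84 for 2 and 3; peaks are not independent replicates.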

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

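The analyses of weaker peaks and the test on tRNA genes were chosen only after the results they concern had been seen.

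The pooled list held 5250 peaks with a q value of 0.05 or less below the IDR threshold, outside the peaks tested in the report. Their summits lay in promoters in 33.2% of cases, 2.45 times chance, and in coding sequence in 27 cases, 0.0375 times chance (circular-shift permutation, two-sided, adjusted p = 0.0035 for both). On dm3, 10 IDR-thresholded peaks lay on scaffolds outside the 6 arms: 6 on 3LHet, 2 on XHet and 2 on Uextra.

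AT-rich sequence at the summits may have technical sources. It was not limited to promoters: outside them the summit exceeded its flanks by 10.3 percentage points (95% bootstrap interval 9.98 to 10.7). Promoter summits lay 5.08 points above the same offsets at start sites without a pooled peak within 500 bp. Those start sites were not matched on kind of gene, so a difference between kinds of promoter stays open. Recovery of AT-rich fragments stays open: over 200 bp on either side the IDR-thresholded peaks exceeded the weakest 9080 pooled peaks by 4.28 points, but such recovery would itself raise signal, by which these sets were split. The composition of the control stays open too, and no biological explanation was tested, because the design has a single group.

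The near absence of summits from coding sequence could reflect base composition. Positions outside promoters matched to the summits on AT share fell in coding sequence in 3.98% of cases, against 15.8% unmatched and 0.289% observed. Matching on composition within 50 bp thus narrowed the gap and left the observed share below the matched one. It used the AT share of the summits themselves, so it cannot show whether composition caused any of the gap. Mappability argued the other way, as unique 31-mers were 15.8 percentage points more frequent in coding sequence than in introns and intergenic sequence. Among the 14273 pooled peaks with a q value above 0.05, coding sequence held 1044 summits (7.31%, 0.534 times chance), so it was not masked as a whole; in the library lists the ratio was 0.542, 0.933 and 0.747 for replicates 1, 2 and 3, so weak peaks of replicate 2 were little depleted. Whole peaks avoided it too, with 0.302% of their bases in coding sequence outside promoters against 13.7% of arm bases, and masking of part of it, composition over longer windows and the control stay open, and no biological explanation was tested.

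The frequent binding of housekeeping promoters could come from signal that gathers at any highly transcribed gene. Among tRNA genes with unique flanks 8.46% had a summit within 500 bp, below the 22.5% of other genes (two-sided Fisher's exact test, p = 1.65e-09), and all tRNA genes, at 7.93%, were not past circular shifts, at 5.3% (permutation, adjusted p = 0.345). These shares lie far under the 83.5% of cytosolic ribosomal protein genes, so tRNA genes as a set did not carry such signal. The low share of tRNA genes was known when the test was chosen, and their transcription was not measured. The test therefore cannot decide on signal at genes of every polymerase. Gene density under placement without regard to promoters fell short of that share: shifted peaks reached at most 15.3% of cytosolic ribosomal protein genes. Shifting also takes away the general gathering at promoters, and 22.3% of all genes were bound. It therefore cannot tell whether gene density matters for a protein that gathers at promoters. Signal tied to transcription, including that by RNA polymerase II alone, stays open, since no expression data were used here.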

How the results depend on the processing

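Of 845 recomputed values, 747 counted as unchanged. These kept their side of the threshold, moved by no more than the spread or, for counts, stayed of similar size. Some turned in direction with neither value past the test, such as the non-coding exon share with 1000 bp, at 0.957 times chance. Ranks of named genes made up 303 of the 747. Leaving out a replicate cannot move a mean of 3 libraries past their SD, so those 303 could not change. This also held for peak reproducibility without each replicate. Also among the 747 were the promoter, coding, 3′ UTR and intergenic shares under every setting tried, the difference in signal and the low density on chromosome 4. The alternatives on weaker pooled peaks and on mappable genes were chosen only after seeing the data. The dm3 alternative for arms was not run, because lengths of the dm3 arms were not used here. No paired analysis was possible because there is a single group. Read depth was unknown, so its effect on the lists cannot be given. Except where stated, the cause was not tested.

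With at least 50% of both peaks overlapping, 74.9% of the IDR-thresholded peaks were shared with the strongest peaks of a library and 83.3% with its whole list. In the 3858 peaks with the highest signal the share was 98.6% and the mean rank correlation 0.852. Over the pairs left without each replicate the correlation ranged from 0.84 to 0.849.

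In those 3858 peaks the arm ratios were 0.939 for 2R and 1.03 for X, neither past the test. With genes in place of length 2L turned to 0.911 and 3L rose past the test at 1.1. The intron share turned to 1.06 times chance with a 250 bp window, fell past the test at 0.896 with 1000 bp, and was 1.06 in the 5250 weaker pooled peaks, where the 5′ UTR share was 0.783 and that of non-coding exons 1.45.

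The number of lists bound more often, 8 in the report, was 3 in the 3858 strongest peaks and 5 against protein-coding genes, and 5 to 6 without each replicate (lowest without replicate 3). The number bound less often, 9, was 5 in the strongest peaks and 2 against circular shifts; fewer peaks or genes enter the former settings. Against shifts, cytochrome P450, tRNA and snoRNA genes turned to 1.15, 2.64 and 1.03 percentage points above chance.

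The number of more frequent motifs, 8, was 4 at peaks outside promoters; that of scarcer ones, 6, was 2 against shuffled windows and 3 in the weaker pooled peaks. Against shuffled windows the ratios of the GAGA factor, CAGCTG, CTCF and CA repeat motifs turned to 1.76, 2.36, 2.49 and 1.83. At promoter peaks alone Pho turned to 1.05 and CTCF to 1.46, and at other peaks Ohler motif 7 turned to 0.799. The 8-mers called more frequent and scarcer, 2896 and 4178, were 735 and 629 at promoter peaks, 1711 and 1754 at other peaks, and 1383 and 1415 in the strongest 3858, each with fewer peaks.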

Other observations

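The tests on divergent genes and on disc patterning genes were written down before their results were seen; the other values below were chosen after the data were seen.

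Of the 10 strongest reproducible peaks outside promoters, 8 lay within genes and 2 between genes (ranks 13 and 24). The peak that ranked 2 of 7717, and 2 in each library, lay in an intron of ush, a cofactor of GATA factors, on 2L from 480575 to 481330. Others lay in an intron of the kinase gene Lk6 (rank 7), in introns of CG32486 (rank 9), CG11050 (rank 14) and CG32772 (rank 18), in the locus of osa, a Brahma complex subunit (rank 11), in an intron of both HmgD and HmgZ (rank 16) and in an intron of Eip75B, an ecdysone response gene (rank 19), 12087 bp from the nearest start site. By kind of gene, 3681 of 13945 protein-coding genes (26.4%), 310 of 3261 non-coding RNA genes (9.51%) and 11 of 268 pseudogenes (4.1%) had a promoter peak.

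Protein-coding genes with another protein-coding gene starting within 1000 bp upstream on the other strand carried a promoter peak in 2359 of 5052 cases (46.7%), against 14.9% of the other 8893. The difference was 31.8 percentage points (one-sided upper tail of Fisher's exact test, log10 p of −358). A pair of start sites hit independently at the rate of the other genes would reach 27.5%, below the 95% Wilson interval of 45.3% to 48.1%. Start sites per gene were not counted, and 1 summit can mark both genes of a pair, while the test and the interval treat genes as independent. Whether divergent promoters are bound more often than their number of start sites gives thus stays open. The 1524 promoter peaks near divergent genes carried the DRE in 5.45% of cases against 2.12% of the other 1699 (adjusted p = 5.16e-06, Fisher's exact test), and the GAGA factor motif in 0.656% against 1.65% (adjusted p = 0.0448).

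Imaginal disc patterning genes, with 1 promoter peak among 34 genes, might hold peaks elsewhere. In these genes and the 5 kb around them lay 65 summits outside promoters, against a mean of 58.3 over 1000 circular shifts (permutation, two-sided, p = 0.625), so an excess was not detectable.

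Promoter peaks with a DRE had a lower median signal value than those without, 176 against 225 (permutation test with 100000 resamples, two-sided, p = 0.0203, 119 and 3104 peaks). On dm3, the whole list of replicate 2 held 197 peaks outside the 6 arms, 76 of them on 2RHet and 65 on 3LHet, against 49 in replicate 1 and 60 in replicate 3. Chromosome X held 17.8%, 14.4% and 18.9% of the whole dm6 lists of replicates 1, 2 and 3.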
